A study of Sus scrofa with 30 samples.

How the data were processed

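Expression was measured on 30 Affymetrix Porcine Genome arrays, 1 array per tissue sample, from teats of 10 pigs taken at slaughter. The labels give a mean end weight of 110 kg and 500 ng of total RNA per labelling reaction. Each array carries an animal number, a tissue (epithelial or mesenchymal), a teat type (normal or inverted) and an affection status of the animal. These labels form 6 groups of 5 arrays: for each tissue, normal teats of 5 non-affected animals, normal teats of 5 affected animals and inverted teats of the same 5 affected animals. The animal numbers were taken from the sample descriptions. They were taken to pair the arrays, which was checked: after removal of the group means, the arrays of both teats of an animal correlated with r from 0.24 to 0.54 in epithelial and from 0.14 to 0.67 in mesenchymal tissue, and the animal's own array was the best match in 5 of 5 and 4 of 5 animals. Across tissues the pairing was weaker: r ran from 0.02 to 0.69 in non-affected animals (best match in 4 of 5), from 0.01 to 0.42 in normal teats of affected animals (3 of 5) and from -0.03 to 0.62 in inverted teats (2 of 5).

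The deposited values are probe set summaries on a log2 scale for 24123 probe sets. The base of the logarithm was inferred from the range of the values, since no label states it. GCOS 1.1.1 and PLIER are named in the submitters' processing notes, which do not say what each was used for. The lowest value is 0, and 358 to 754 probe sets per array lie at it. Array medians lie between 5.71 and 6.04, and no label states whether the arrays were normalised to one another; the values were therefore used as deposited. A total of 17 values in 4 probe sets exceed 16, with a highest value of 20.8. The number of arrays limits the precision of every comparison.

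Gene names came from the platform table matched by Entrez ID to a RefSeq gene table. Exactly 1 symbol was found for 10099 probe sets, several for 198, and none here for 13826. The single-symbol probe sets cover 6765 symbols, and the Entrez IDs of 9989 of them were found in the RefSeq table. Each gene is represented by its probe set with the highest mean over the 30 arrays. No genome was used, so no coordinates are given. TBX3, MSX2, KRT14 and COL1A1 have no single-symbol probe set and were not analysed here.

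The comparisons, gene lists, filter and alternatives were fixed before the data were examined. All tests across probe sets were run with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p; 124 control probe sets were left out. A probe set was tested where it lay above its array's 30th percentile in at least 5 arrays of the fit. Epithelial and mesenchymal tissue were fitted apart (15 arrays each, group means only). The tissue comparison used the 20 arrays of normal teats with affection status as a covariate. Whether a teat difference differed between tissues was tested as an interaction over all 30 arrays. The animal was not a term of these fits, and it entered as a replicate block in an alternative.

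A set of 23 gene lists covers the cell types a teat sample can hold and the pathways of teat growth, hormone action, stress and housekeeping. Each was tested per teat comparison with limma's camera, two-sided, at a preset inter-gene correlation of 0.01, and adjusted over all 132 tests. Lists with under 5 tested genes were left out of a test, and every call was repeated with the correlation estimated from the data. For each called list the array means of its members were compared with a two-sided exact permutation test over the 10 arrays of the comparison. The smallest p that test allows is 0.00794, or 0.0625 with the signs exchanged within 5 animals. A list of 10 sex-linked genes was kept for a check of the samples; only 2 were measured and they did not part the arrays.

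The genes to be named were set by rule. For each teat comparison these were the 6 highest and 6 lowest by log2 difference past the threshold, filled from the smallest p up to 3 per direction where fewer passed. To these were added the 2 members of each called list with the smallest p in its direction, and PTHLH, PTH1R, LEF1 and MSX1 wherever tested. A gene chosen by its p is likely to go the same way in most animals, so that count is no separate support. For the tissue comparison they were the 5 largest differences per direction and 2 members per list, and for the differences between tissues the 3 smallest p. Genes named outside this rule are marked as chosen after their values were seen. Errors are SD over animals for group means, and SE from the fit for differences.

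The fits were tested on simulated data with 200 changed probe sets and a correlation of 0.4 between arrays of an animal. For inverted against normal teats of affected animals, 68.7% of simulated differences of 1 on the log2 scale were recovered in epithelial tissue (17661 probe sets) and 28.4% in mesenchymal tissue (17839 probe sets); of differences of 0.5, 4.48% and 1.49% were recovered. With the animal as a replicate block 83.6% and 61.2% of the differences of 1 were recovered, while 12 and 13 unchanged probe sets were called, against 0 and 2 without the block. A shift of 0.5 in all members of 1 list was called by camera in all 6 teat comparisons, with either correlation. The simulated genes varied independently of one another, whereas the called lists had estimated correlations from 0.18 to 0.70. The simulated shift therefore cannot tell how camera performs on lists of correlated genes. Alternatives were quantile normalization, an added offset of 16 before the logarithm, other filters, an unmoderated linear model, array weights, breed as a covariate or only the largest breed cross, other sets of samples in the fit, the animal as a random or fixed replicate block, another probe set summary per gene, and each animal left out in turn. After the data had been seen, 4 more were added: the epithelial inverted teat array of animal 1103 left out, the mesenchymal arrays of animal 963 (inverted teat) and animal 1040 left out, the CSN2 level as a covariate, and the mean of KRT8, KRT18 and KRT19 as a covariate.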

Results

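Gene expression was profiled in the epithelial and the mesenchymal tissue of pig teats. The 10 animals comprised 5 without inverted teats and 5 with at least 1 inverted teat. A normal teat was sampled from every animal and an inverted teat from each of the 5 affected animals, so each of the 6 combinations of tissue, teat type and affection status held 5 arrays. Animals 957 and 963 were German Landrace, 1103 and 1109 Pietrain x (Large White x German Landrace), and the other 6 Large White x German Landrace. The series addresses which genes bear on the predisposition to inverted teats. Median log2 values per array lay between 5.71 and 6.04, and each array's median correlation with the arrays of its tissue was between 0.888 and 0.939.

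The tissue comparison shows which genes mark each dissected layer in normal teats. Mesenchymal pieces carried far more transcript of striated muscle. MYLPF, a fast muscle myosin light chain, was lower in epithelial tissue by a log2 difference of -7.52 ± 1.74 (SE, n = 10 animals, 10 of 10 in this direction, adjusted p = 0.0030), and TNNT3, a fast troponin, by -7.52 ± 1.61 (9 of 10 animals, adjusted p = 0.0017). MYH2, KLHL41 and TNNC2 followed with -7.02 ± 1.72, -6.55 ± 1.21 and -6.44 ± 1.42 (SE). In epithelial pieces the largest excess was in LOC100737483 with 4.76 ± 1.29 (SE), in NPG4, a protegrin antimicrobial peptide, with 4.68 ± 0.81, and in MMP7, a protease of glandular epithelium, with 4.41 ± 1.0 (adjusted p = 0.0026). WFDC2, a protease inhibitor secreted by glandular epithelia, had 4.05 ± 0.95 and the carbonyl reductase CBR1 4.02 ± 1.33 (adjusted p = 0.025, 9 of 10 animals). CBR1 no longer passed without animal 1059, 1103 or 1109. Other probe sets of NPG4 and WFDC2 gave differences of -0.03 and 0.03. The size of these differences depends on values near background: the 5 muscle genes lay under the 30th percentile of the array on 6 to 7 of 10 epithelial arrays, and the 5 genes higher in epithelium on 3 to 6 of 10 mesenchymal arrays.

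Among the gene lists, skeletal muscle, adipocyte and respiratory chain genes were nearly all higher in mesenchymal tissue. Of 29 measured skeletal muscle genes, 27 were higher there (median -4.89). The same held for 19 of 21 adipocyte genes (median -1.83), with GPD1 at -3.82 ± 0.41 (SE) and CIDEA, a lipid droplet protein, at -2.44 ± 0.32. Of 58 respiratory chain genes, 55 were higher in mesenchymal tissue (median -0.76), with NDUFA9 of complex I at -1.33 ± 0.16 and the ATP synthase subunit ATP5A1 at -0.96 ± 0.10. With quantile normalization 44 of the 58 were higher in mesenchymal and 1 in epithelial tissue. The lipogenic enzymes FASN and SCD, -1.58 ± 0.25 and -1.25 ± 0.19, made up both mesenchymal genes of the 5 on the hair and gland list, where 1 was higher in epithelium. DES and PDLIM3, structural proteins of muscle, were 2 of 4 smooth muscle list members higher in mesenchymal tissue (-2.65 ± 0.49 and -2.62 ± 0.53), against 1 of 25 higher in epithelium. With quantile normalization 5 smooth muscle list members were higher in each tissue. The growth hormone receptor GHR, -1.47 ± 0.21, and HSD17B4, -1.45 ± 0.21, were 2 of 7 genes of the steroid, prolactin and growth hormone list higher in mesenchymal tissue, and 6 of its 24 were higher in epithelium.

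Epithelial tissue was higher in 9 of 19 genes of the mammary luminal and milk list (median 1.30), and mesenchymal tissue in 3, which included STAT5B at -0.93 ± 0.16 (SE) and STAT5A at -0.52 ± 0.13. Other probe sets of STAT5A gave -0.46 and 0.05. Chosen after their values were seen, the luminal keratins KRT19 and KRT18 had 3.55 ± 1.11 and 3.14 ± 1.02, and lactoferrin, LTF, 3.92 ± 1.02. The keratin difference was not shared by all animals. In normal teats of animals 950, 957, 963 and 964 the mean of KRT8, KRT18 and KRT19 was 9.67 to 10.66 in epithelial and 9.15 to 10.65 in mesenchymal tissue. In mesenchymal normal teats of the other animals it was 2.38 to 7.28. Of 16 keratinocyte genes, 6 were higher in epithelium and 1 in mesenchyme, with the desmosomal DSP at 2.63 ± 0.74 and PERP at 1.90 ± 0.57. Among 20 teat and mammary bud development genes, 6 were higher in epithelium and 4 in mesenchyme, the latter including HOXD8 at -0.83 ± 0.15. Those higher in epithelium included PTHLH, the hormone that induces the mammary mesenchyme, at 1.08 ± 0.41 (adjusted p = 0.049, chosen after its value was seen). The Wnt list of 15 had 3 higher in epithelium, with the co-receptor LRP6 at 0.44 ± 0.12, and 1 in mesenchyme, FZD4 at -1.17 ± 0.20. Fibroblast and matrix genes divided, with 5 of 38 higher in epithelium, such as ASPN at 1.31 ± 0.33, and 4 in mesenchyme, such as MFAP5 at -0.63 ± 0.16; with quantile normalization the split was 19 and 1, and MFAP5 no longer passed.

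The remaining lists had few members past the threshold. Higher in epithelial and mesenchymal tissue, respectively, were 4 and 3 of 23 TGF-beta and BMP genes, 1 and 5 of 28 growth factor and receptor genes, 2 and 4 of 15 basement membrane genes, and 2 and 4 of 29 cell cycle genes. The immediate early and heat shock list had 1 and 6 of 34, the Schwann cell list 1 and 2 of 9, and the interferon list 2 and 0 of 26. Of the leukocyte, inflammatory, endothelial and ribosome lists 1 gene each was higher in mesenchyme, of 27, 18, 19 and 57, and of 5 melanocyte genes none passed. With quantile normalization 12 ribosome genes were higher in epithelium. The growth factor and basement membrane splits turned with it, to 7 and 4 and to 5 and 1. Adjusted over the list alone, 27 skeletal muscle, 19 adipocyte, 57 respiratory chain and 14 luminal and milk genes passed.

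**Figure D1:**
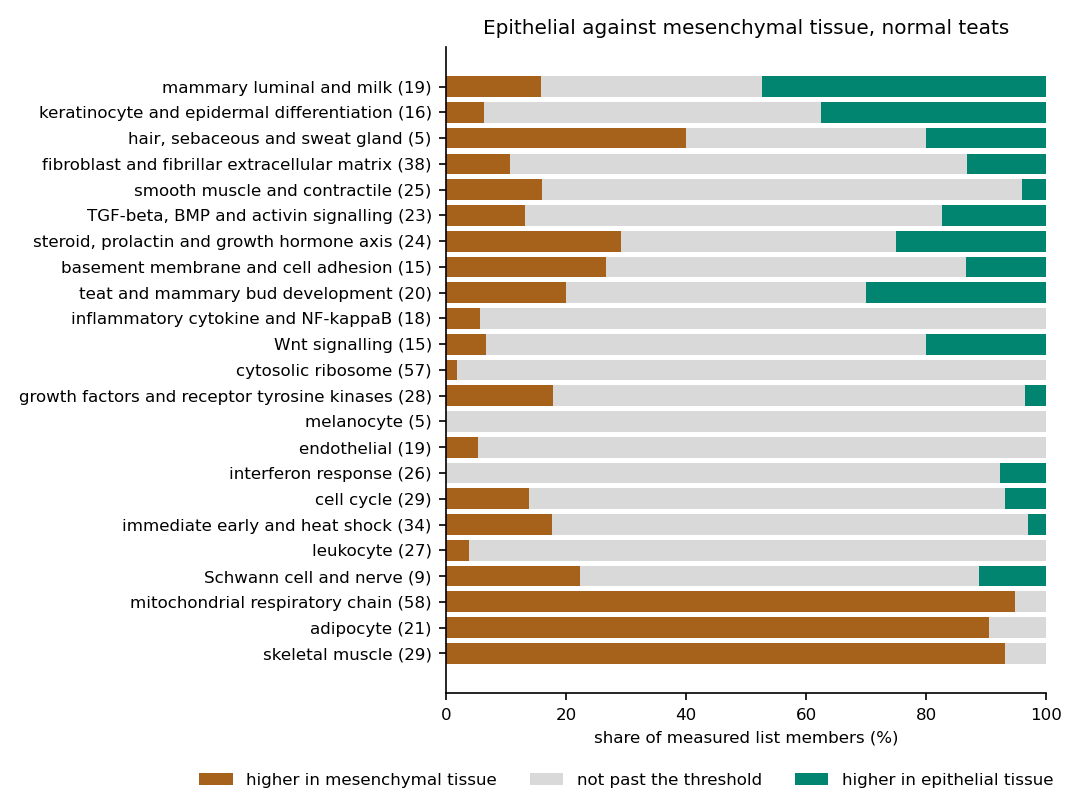
Share of the measured members of each gene list (horizontal axis, percent; number of members in parentheses) that were higher in mesenchymal tissue, higher in epithelial tissue or not past an adjusted p of 0.05, in the normal teats of 10 animals. Of the skeletal muscle, adipocyte and respiratory chain lists, 27 of 29, 19 of 21 and 55 of 58 genes were higher in mesenchymal tissue.

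Over all 18286 probe sets tested with limma, 6122 passed the threshold, 2360 higher in epithelial and 3762 higher in mesenchymal tissue. With the animal as a replicate block the count was 8124 as a random and 7805 as a fixed term. The directional split depended on scaling: with quantile normalization 3484 were higher in epithelial and 2888 in mesenchymal tissue, or 54.7% against 38.5% higher in epithelium as deposited. The medians of the endothelial, Wnt, growth factor, immediate early and ribosome lists changed sign with it, whereas those of skeletal muscle, adipocytes and the respiratory chain kept theirs.

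Among milk protein genes, CSN2 differed far more between animals than between tissues (-0.58 in normal teats, adjusted p = 0.86). CSN2, beta-casein, measured 12.94 to 16.17 on every array of animals 950, 957, 963 and 964, of which 950 and 957 were non-affected and 963 and 964 affected, and 4.0 to 6.39 on the arrays of the other 6 animals. These ranges were drawn up after the values had been seen, and no test was made on them.

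**Figure D2:**
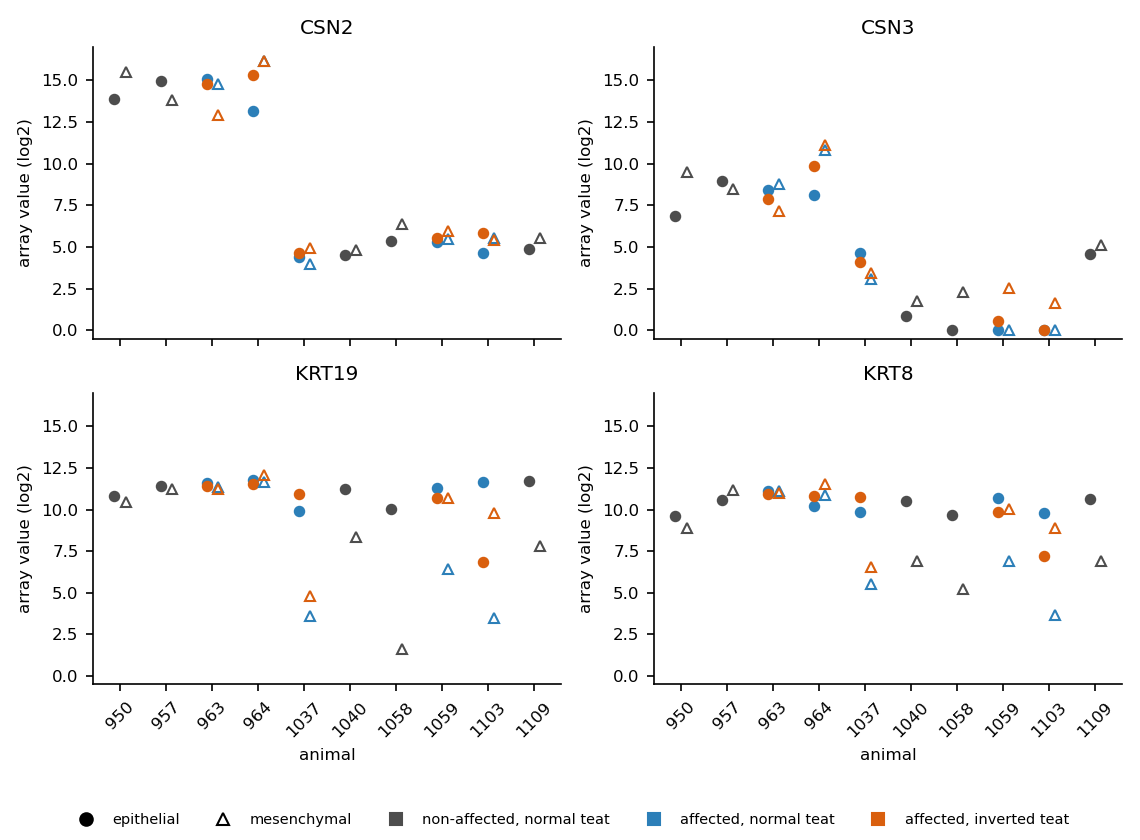
Log2 values of the milk protein genes CSN2 and CSN3 and the luminal keratins KRT19 and KRT8 on each array (points), by animal (horizontal axis), tissue (shape) and teat type with affection status (color). CSN2 lay between 12.94 and 16.17 on the arrays of animals 950, 957, 963 and 964, and KRT19 between 1.61 and 12.05 in mesenchymal tissue.

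Inverted and normal teats of the same affected animals were compared in epithelial tissue to find genes that go with the inverted teat itself. Skeletal muscle genes had higher values in the inverted teats: 24 of 25 tested members, with a median log2 difference of 1.49. The median was 0.96 without animal 964 and 0.97 without animal 1037, and up to 1.51 with other animals left out; over the whole list, the means of these 2 animals differed by 3.50 and 2.67, against -0.35, 0.06 and 0.84 in animals 963, 1059 and 1103. ACTN2, a sarcomeric alpha-actinin, measured 6.20 ± 0.47 in inverted and 5.68 ± 0.49 in normal teats (SD, n = 5 animals), and MYH7, the slow muscle myosin, 5.64 ± 0.29 and 5.14 ± 0.19, each higher in 5 of 5 animals. All 25 smooth muscle and contractile genes had higher values (median 0.24), among them MYOCD, a coactivator of smooth muscle genes, with a difference of 0.36 ± 0.25 (SE) and CALD1 with 0.24 ± 0.21. All 56 ribosome genes had lower values (median -0.10), for example RPL35 with -0.17 ± 0.10 and RPL26 with -0.25 ± 0.16, as did 54 of 58 respiratory chain genes (median -0.11), for example NDUFA13 with -0.21 ± 0.13 and ATP5E with -0.19 ± 0.12. Of 19 endothelial genes 15 were higher (median 0.12), with the VEGF receptor FLT1 at 0.32 ± 0.21 and the transcription factor ERG at 0.25 ± 0.27.

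These 5 lists were called by limma's camera at the preset correlation, with adjusted p of 4.3e-10 for skeletal muscle, 2.6e-06 for both smooth muscle and the ribosome, 0.00036 for the respiratory chain and 0.045 for endothelial genes. None was called when the correlation was estimated (adjusted p = 0.97 with an estimated correlation for each). On array means of the whole lists, the two-sided exact permutation test within animals gave p = 0.0625, the smallest it can give with 5 animals, for smooth muscle (5 of 5 animals higher) and the ribosome (5 of 5 lower). It gave 0.1875 for skeletal muscle, higher in 4 of 5 animals, 0.25 for the respiratory chain, lower in 3 of 5, and 0.75 for endothelial genes, higher in only 2 of 5. On the epithelial inverted teat array of animal 1103 the smooth muscle list lay 6.89 SD above the median of the other epithelial arrays and the endothelial list 3.33 SD above it, while the keratinocyte list lay at -7.26 SD and the mammary luminal and milk list at -3.45 SD. Without both teats of animal 1103 the smooth muscle median was 0.08 (0.08 to 0.31 over the animals left out) and the endothelial median -0.04; without that array alone, which breaks the pair, they were -0.05 and -0.04. With the mean of KRT8, KRT18 and KRT19 as a covariate they were 0.015 and -0.045. That mean was 6.75 on the same array and 9.27 to 10.66 on the other epithelial arrays, so this setting largely repeats leaving the array out. In none of these 3 settings was either list called. The endothelial call was also lost without animal 963 or 1040 (medians 0.08 and 0.12) and with no filter. With quantile normalization the ribosome list had a median of -0.03 and was not called (adjusted p = 0.59).

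No single gene passed the threshold. The smallest p among higher values belonged to SYT5, a synaptotagmin of secretory vesicles, at 0.57 ± 0.17 (SE), the Mediator subunit MED9 at 0.40 ± 0.12 and the tRNA phosphotransferase TRPT1 at 0.32 ± 0.10; among lower values to FAM122A at -0.39 ± 0.13, the actin-binding AIF1L at -0.75 ± 0.26 and SSBP2 at -0.38 ± 0.13. Each of these 6 went the same way in 5 of 5 animals, which their choice by the smallest p in the same animals makes likely. Of the teat development genes, PTHLH differed by -0.47 ± 0.48, MSX1, a homeobox gene of the mammary bud, by -0.33 ± 0.20, PTH1R, the PTHLH receptor, by 0.19 ± 0.23 and LEF1, a Wnt transcription factor, by 0.08 ± 0.45; PTHLH stood at 4.66 on the inverted teat array of animal 1103 against 6.93 to 7.59 in the other 4, and without this animal the PTHLH difference was -0.08. Of 17661 probe sets tested with limma 0 passed, 303 had an unadjusted p under 0.05, and with the animal as a replicate block these counts were 0 and 992. A share of 0.05 of the probe sets is 883. In the fit without the animal, other exchanges of teats within animals did not reach that number either (highest other 490). No list member passed when adjusted over the list alone.

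**Figure D3:**
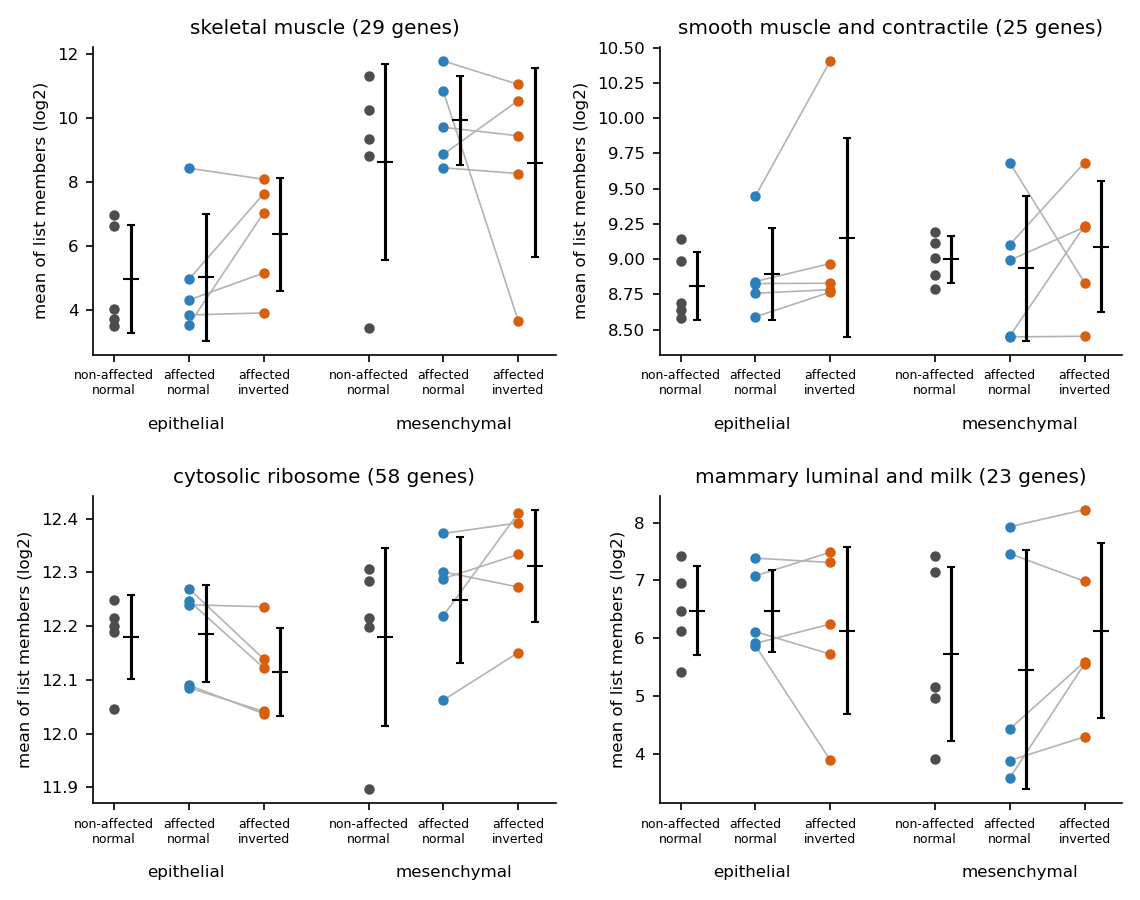
Mean log2 value over all members of 4 gene lists on each array (points), by tissue, teat type and affection status; bars give the mean and SD of 5 animals, and grey lines join the teats of an affected animal. The mesenchymal skeletal muscle means ranged from 3.44 to 11.78, with the mesenchymal inverted teat of animal 963 at 3.67 and the mesenchymal normal teat of animal 1040 at 3.44.

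Normal teats of affected and non-affected animals were compared in epithelial tissue, where a difference would go with the animal's status and not with the teat's form. Leukocyte genes had higher values in affected animals (24 of 28, median 0.18), with JCHAIN, the joining chain of secreted immunoglobulin, at 6.98 ± 1.11 against 5.50 ± 1.15 (SD, n = 5 per group) and the neutrophil and macrophage protein S100A9 at 5.37 ± 1.09 against 4.37 ± 0.65; without animal 1037 the S100A9 difference of 1.0 was 0.53. Immediate early and heat shock genes had lower values (27 of 34, median -0.13): the transcription factors EGR1 and ATF3 differed by -1.34 ± 0.72 and -0.86 ± 0.46 (SE). Respiratory chain genes were higher in 46 of 58 (median 0.07), with ATP5O at 0.27 ± 0.11 and NDUFA13 at 0.22 ± 0.13.

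The 3 lists were called by camera, with adjusted p of 0.046, 0.046 and 0.0073, and none was with an estimated correlation (adjusted p = 0.97 for each with an estimated correlation). The exact permutation tests on array means gave p = 0.33 for leukocytes, 0.30 for immediate early genes and 0.56 for the respiratory chain, two-sided. Leaving out 1 animal ended these calls for 5, 6 and 3 of the 10 animals; without animal 963 the leukocyte median was 0.02, without animal 964 the immediate early median was -0.07, and without animal 1037 the respiratory chain median was -0.0041. The leukocyte call was also lost with quantile normalization and the immediate early call with no filter, and both with the keratin mean as a covariate (medians 0.15 and -0.14). No gene passed: higher in affected animals with the smallest p were the zinc-finger protein ZNF335 at 0.62 ± 0.13 (SE), the carbonyl reductase CBR2 at 1.14 ± 0.34 and the aminopeptidase XPNPEP2 at 0.47 ± 0.15, and lower were PPP2R2B, a regulatory subunit of protein phosphatase 2A, at -1.05 ± 0.27, RABL3 at -0.72 ± 0.22 (-0.09 on its other probe set) and DNTTIP2 at -0.43 ± 0.14. PTHLH, MSX1 and LEF1 differed by 0.06 ± 0.48, 0.08 ± 0.20 and -0.25 ± 0.45, and PTH1R measured 5.48 ± 0.37 and 5.49 ± 0.22 (SD). With limma 0 of 17661 probe sets passed, 420 had an unadjusted p under 0.05, and the fit with the animal as a replicate block gave 0 and 391; adjusted over the list alone, 0 members of any list passed.

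Inverted teats of affected animals were also set against the normal teats of non-affected animals in epithelial tissue. All 25 tested skeletal muscle genes had higher values in the inverted teats (median 1.47); ACTN2 differed by 0.76 ± 0.24 (SE) and MYH7 by 0.70 ± 0.26. Smooth muscle genes were higher in 24 of 25 (median 0.25), with PDLIM3 at 8.01 ± 0.90 against 6.89 ± 0.45 (SD, n = 5 per group) and desmin, DES, at 8.29 ± 1.64 against 6.93 ± 1.02. Endothelial genes were higher in 16 of 19 (median 0.20), with FLT1 at 0.53 ± 0.21 (SE) and CDH5, the endothelial cadherin, at 0.26 ± 0.19. Ribosome genes were lower in 53 of 56 (median -0.12), with RPS25 at -0.22 ± 0.11 (0.11 on its other probe set) and RPL6 at -0.17 ± 0.10.

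Camera called these 4 lists with adjusted p of 6.9e-11, 1.4e-06, 0.00057 and 8.9e-07, and none with an estimated correlation (adjusted p = 0.97 with an estimated correlation for each). On array means the exact permutation tests gave p = 0.22 for skeletal muscle, 0.42 for smooth muscle, 0.37 for endothelial genes and 0.22 for the ribosome. Without the epithelial inverted teat array of animal 1103, on which smooth muscle and endothelial genes were high, the smooth muscle median was -0.03 and the endothelial median 0.07, and neither list was called; with the keratin mean as a covariate the endothelial median was 0.10 and was not called, and with quantile normalization the ribosome median was -0.01 and the list was not called. Leaving out 1 animal gave skeletal muscle medians from 0.79 to 2.02, all called.

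CHGB, a secretory granule protein, had the smallest p among genes higher in inverted teats, 5.03 ± 0.22 against 4.33 ± 0.20 (SD, n = 5), followed by RIBC2 with a difference of 0.47 ± 0.13 (SE) and ZNF335 with 0.47 ± 0.13. The collagen-folding isomerase FKBP14, the ERK phosphatase DUSP6 and RWDD3 were lower, by differences of -0.58 ± 0.16, -0.58 ± 0.17 and -0.61 ± 0.20. Other probe sets gave -0.25 and -0.29 for FKBP14 and -0.29 for DUSP6. CHGB lay under the 30th percentile of the array in 5 of 5 non-affected animals. None of the 6 passed the threshold. PTHLH differed by -0.41 ± 0.48 (0.12 without animal 1103), MSX1 by -0.25 ± 0.20, PTH1R by 0.18 ± 0.23 and LEF1 by -0.17 ± 0.45. Of 17661 probe sets tested with limma 0 passed and 484 had an unadjusted p under 0.05; with the animal as a replicate block the counts were 0 and 441. Adjusted over the list alone, 0 members of any list passed.

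In mesenchymal tissue, inverted teats of affected animals had lower values of skeletal muscle genes than their normal teats, in 28 of 29 members (median -1.38). TNNC1, the slow muscle and heart troponin C, measured 6.19 ± 3.38 in inverted and 8.36 ± 1.70 in normal teats (SD, n = 5 animals), and the slow myosin light chain MYL2 5.96 ± 3.09 and 7.64 ± 2.0, each lower in 3 of 5 animals. Mammary luminal and milk genes had a median difference of 0.71 but were not called (adjusted p = 0.14). CST6, a protease inhibitor of the epidermis, was 7.31 ± 0.47 in inverted and 6.44 ± 0.46 in normal teats, higher in 5 of 5 animals, the peptide transporter SLC15A2 differed by 0.47 ± 0.15 (SE; -0.12 on its other probe set) and the endothelin receptor EDNRB by 0.43 ± 0.15. FOXA2, a transcription factor of endodermal epithelia, differed by -0.74 ± 0.24, TSPAN17 by -0.54 ± 0.20 and CFAP126, a cilium protein, by -1.19 ± 0.46, with CFAP126 under the 30th percentile of the array in 5 of 5 inverted teats.

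Skeletal muscle was the 1 list called of 22, with an adjusted p of 1.2e-13 at the preset correlation and adjusted p = 0.97 with an estimated correlation; the exact permutation test within animals gave p = 0.56. The mesenchymal inverted teat of animal 963 had a list mean of 3.67 against 10.83 in its normal teat, and without animal 963 the median was 0.25 and the list was not called. None of the named genes passed the threshold, and PTHLH, PTH1R and MSX1 differed by 0.31 ± 0.70, 0.10 ± 0.41 and -0.43 ± 0.29 (SE). With limma 0 of 17839 probe sets passed and 78 had an unadjusted p under 0.05. A share of 0.05 of the probe sets is 892, which other exchanges of teats within animals did not reach in this fit either (highest other 459). With the animal as a replicate block the counts were 0 and 535. Adjusted over the list alone, 0 members of any list passed.

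Between normal teats of affected and non-affected animals, mesenchymal tissue had higher values of skeletal muscle genes in affected animals in 28 of 29 members (median 1.22). TNNI1 and TNNT1, slow muscle troponins, measured 6.63 ± 1.90 and 7.23 ± 2.15 in affected against 4.39 ± 2.62 and 4.66 ± 2.79 in non-affected animals (SD, n = 5 per group). Cell cycle genes were higher in 22 of 28 (median 0.15), including cyclin B1, CCNB1, with 0.55 ± 0.27 (SE) and UBE2C, which acts in mitotic exit, with 0.80 ± 0.46. Ribosome genes were higher in 48 of 57 (median 0.08), with RPS15 at 0.20 ± 0.14 and RPL13 at 0.19 ± 0.15. TACC3, a mitotic spindle protein, had the smallest p of any named gene here, 5.44 ± 0.34 against 4.21 ± 0.75 (SD, n = 5).

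Camera called the 3 lists with adjusted p of 0.00037, 0.035 and 0.0093, and none with an estimated correlation (adjusted p = 0.97 with an estimated correlation for each). The exact permutation tests on array means gave p = 0.51, 0.44 and 0.47. The mesenchymal array of animal 1040 held little skeletal muscle transcript, and without this animal the muscle median was -0.13; without animal 1059 it was 0.72 and the call was also lost. The cell cycle call was lost without animal 963, 964, 1037, 1040, 1058 or 1109, with medians of 0.12, 0.12, 0.13, 0.12, -0.0029 and 0.20, and with the mean of all probe sets per gene (0.07). The ribosome call was lost without animal 964, 1037 or 1058, with medians of 0.06, 0.08 and 0.0097, and with quantile normalization (0.03). Also among the smallest p were LOC100152327 at 2.08 ± 0.76 (SE) and the enteropeptidase gene TMPRSS15 at 0.46 ± 0.17, higher, and the magnesium transporter SLC41A1 at -0.64 ± 0.23 (0.18, -0.01 and 0.35 on its other probe sets), OCIAD2 at -0.63 ± 0.24 and surfactant protein D, SFTPD, at -0.41 ± 0.15, lower. The other probe set of SFTPD gave -0.0039. PTHLH, PTH1R and MSX1 differed by 0.41 ± 0.70, 0.11 ± 0.41 and 0.24 ± 0.29. With limma 0 of 17839 probe sets passed and 201 had an unadjusted p under 0.05, and with the animal as a replicate block the counts were 0 and 159. Without animal 957 TACC3 alone passed, with a difference of 1.56 and an adjusted p of 0.049. Among non-affected animals TACC3 was 5.55 in animal 957 and 3.71 to 3.97 in the others. It lay under the 30th percentile of the array in 4 of 5 non-affected animals, and TMPRSS15 in 5 of 5. The sizes of the TACC3 and TMPRSS15 differences are therefore uncertain. Adjusted over the list alone, 0 members of any list passed.

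Inverted teats of affected animals had higher mesenchymal values of ribosome genes than normal teats of non-affected animals, in 56 of 57 members (median 0.14). RPL13 measured 12.41 ± 0.15 and 12.13 ± 0.15 (SD, n = 5 per group) and RPL14 differed by 0.25 ± 0.14 (SE). Adipocyte genes were lower in 16 of 21 (median -0.17), with lipoprotein lipase, LPL, at -0.33 ± 0.31 and the adipogenic factor CEBPA at -0.49 ± 0.57. ASPA, aspartoacylase, measured 4.87 ± 0.62 against 2.38 ± 1.71 (SD), TMPRSS15 differed by 0.62 ± 0.17 (SE) and SLC35A4 by 0.55 ± 0.17; lower were the ammonium transporter RHBG at -0.84 ± 0.28, OCIAD2 at -0.69 ± 0.24 and FOXA2 at -0.70 ± 0.24 (-0.44 without animal 964). ASPA and TMPRSS15 lay under the 30th percentile of the array in 5 of 5 non-affected animals, and RHBG in 5 of 5 inverted teats, so the sizes of these differences are uncertain.

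The 2 lists were called with adjusted p of 1.0e-05 and 0.0035, and neither with an estimated correlation (adjusted p = 0.97 with an estimated correlation for both). The exact permutation tests on array means gave p = 0.16 for the ribosome and 0.79 for adipocytes. The adipocyte call was lost without animal 964, 1040 or 1109, with medians of 0.14, -0.13 and -0.07. That call was also lost with the keratin mean as a covariate (0.034) and without the mesenchymal arrays of animals 963 (inverted teat) and 1040 (-0.17). The ribosome medians with 1 animal left out ran from 0.07 to 0.18, all called. None of the named genes passed, and PTHLH, PTH1R and MSX1 differed by 0.71 ± 0.70, 0.20 ± 0.41 and -0.19 ± 0.29. With limma 0 of 17839 probe sets passed and 219 had an unadjusted p under 0.05; with the animal as a replicate block the counts were 0 and 167. Adjusted over the list alone, 0 members of any list passed.

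Whether a teat difference was unlike in the tissues was tested directly, as the epithelial minus the mesenchymal difference. For inverted against normal teats within affected animals, the skeletal muscle list had a median of 2.74 (1.53 without animal 963), the ribosome list -0.16 and the respiratory chain list -0.20 (-0.07 without animal 1037 and -0.11 without animal 1103, not called); camera called each at the preset correlation and none with an estimated correlation (adjusted p = 0.48 for skeletal muscle and 0.90 for the other lists with an estimated correlation). HAND1, a transcription factor of heart and other mesoderm, PSMD10, a proteasome subunit, and LOC100511846 had the smallest p, at -0.84 ± 0.29, -0.76 ± 0.26 and 1.11 ± 0.39 (SE). For normal teats of affected against non-affected animals these were ALG14 at -0.97 ± 0.27, the serine protease HPN at -0.83 ± 0.27 and PPP2R2B at -1.48 ± 0.54. For inverted against non-affected normal teats they were the steroidogenic factor NR5A1 at 0.79 ± 0.22, the anion exchanger SLC26A6 at -1.31 ± 0.42 and ASPA at -2.22 ± 0.77. None of these genes passed: with limma 0 of 18783 probe sets passed in each contrast, and 171, 121 and 227 had an unadjusted p under 0.05; with the animal as a replicate block the counts were 0 in each, and 421, 281 and 556. In simulated data these contrasts recovered 14.9%, 23.9% and 23.9% of differences of 1 on the log2 scale among 18783 probe sets. LOC100511846 lay under the array's 30th percentile in 3 to 5 of 5 arrays of every group. ALG14 did in 5 of 5 epithelial normal teats of affected and 4 of 5 of non-affected animals. SLC26A6 did in 5 of 5 epithelial inverted teats and ASPA in 5 of 5 non-affected mesenchymal teats. HAND1 did in 3 of 5 epithelial inverted teats. In mesenchymal normal teats, HPN did in 3 of 5 non-affected and PPP2R2B in 3 of 5 affected animals. The sizes of these genes' differences are therefore uncertain.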

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

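The tests of how often other assignments of the arrays gave counts as large were set before the data were examined; the exchanges with the animal as a replicate block, the differences between tissues with 1 animal left out and the tests of the causes of the milk gene, animal 1103 and skeletal muscle patterns were chosen after the results were seen.

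Teat comparisons fitted without the animal gave no more probe sets at an unadjusted p under 0.05 than many other assignments of the same arrays. In epithelial tissue, 7 of the 16 exchanges of inverted and normal teats within animals gave at least the 303 observed (highest other 490). Normal teats of affected against non-affected animals had 420, reached by 82 of 100 splits (highest other 1711), and inverted against non-affected normal teats 484, reached by 74 of 100 (highest other 2915). In mesenchymal tissue the counts were 78, reached by 15 of 16 exchanges (highest other 459), 201, reached by 95 of 100 splits (highest other 3649), and 219, reached by 86 of 100 (highest other 3706). For the differences between tissues they were 171, reached by 9 of 16 (highest other 241), 121, by 99 of 100 (highest other 1480), and 227, by 70 of 100 (highest other 1593). Fitted with the animal as a random replicate block, the comparisons within affected animals had 992 in epithelial tissue, reached by 6 of 16 exchanges (highest other 1609), 535 in mesenchymal tissue, reached by 13 (highest other 2088), and 421 for the difference between tissues, reached by 9 (highest other 597). With 16 exchanges no share under 0.05 is possible; in the comparisons with 100 splits, chance was not excluded. The highest mesenchymal splits each put animals 950, 957, 963 and 964 on the same side, which points to a structure of the samples other than affection status. In the tissue comparison the real assignment alone of 100 reached 6122 probe sets (highest other 3463, with only animal 963 exchanged), so chance was excluded there.

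Calls of gene lists, adjusted within each comparison, were as frequent under other assignments. In epithelial tissue 11 of 16 exchanges gave at least the 6 lists called within affected animals (highest other 13). The other epithelial comparisons had 3 lists, reached by 83 of 100 splits (highest other 11), and 5 lists, reached by 86 of 100 (highest other 13). In mesenchymal tissue 16 of 16 exchanges gave at least 1 list (highest other 9), 89 of 100 splits at least 4 (highest other 12) and 97 of 100 at least 2 (highest other 15). The 16 exchanges cannot give a share under 0.05, and in the others chance was not excluded.

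Milk protein genes stood high on every array of 4 animals: CSN2, beta-casein, lay between 12.94 and 16.17 on the arrays of animals 950, 957, 963 and 964 and between 4.0 and 6.39 on those of the other 6 animals. A different share of luminal epithelium as the whole cause is argued against in epithelial tissue by the mean of KRT8, KRT18 and KRT19, which ranged by 3.92 over the epithelial arrays (1.40 without the inverted teat of 1103), but not in mesenchymal tissue, where the mean ranged by 8.76 against 12.17 for CSN2 and was 9.15 in 950 and 9.65 in the inverted teat of 1059, with CSN2 at 15.47 and 5.95. Affection status and breed as the whole cause are argued against by ranges of 10.04 in the animal means of CSN2 within a status and 10.7 within the cross of 6 animals. Breed was still uneven: both German Landrace animals (957 and 963) were high and both Pietrain crosses (1103 and 1109) low. Arrays mixed up between animals of different CSN2 level would break the shared level of an animal. That 0 animals had arrays on both sides of the middle of the range restates the pattern as it was seen, so it is no separate test. A mix-up among animals of like CSN2 level was not excluded (own array the best match in 18 of 25 pairs) but would not make the levels. Reproductive state, sex and time of sampling are not in the labels and stay open. The 4 animals with high CSN2 carry the lowest animal numbers, 950 to 964, and the other 6 run from 1037 to 1109. No label says whether the numbers follow the time of sampling. Of 10 sex-linked genes only 2 were measured, with EIF1AY above the 30th percentile on 30 of 30 arrays and SRY on 0, which did not part the animals.

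The epithelial inverted teat array of animal 1103 stood apart from the other 14 epithelial arrays, with a smooth muscle list mean of 10.41 against 8.76 to 8.97 in the other 4 inverted teats. A swap with the mesenchymal array of the same teat is argued against, since that array was the higher in 3 of 3 lists that mark mesenchymal tissue and the respiratory chain list, at 8.96 and 10.26, lay within the other arrays of each tissue (up to 9.39 in epithelial and from 9.51 in mesenchymal tissue); the epithelial markers ran the other way, with the keratinocyte list at 5.59 against 6.64, the luminal list at 3.90 against 5.56 and KRT19 at 6.87 against 9.77. A lower share of epithelium that raises all other cell types alike is argued against by the fibroblast list at -3.57 SD beside smooth muscle at 6.89 SD. A lower share of epithelium as such is not argued against by these values. On the epithelial array the keratinocyte list lay at -7.26 SD and the luminal list at -3.45 SD. More smooth muscle in this piece stays open, with 25 of 25 list members above the median of the other 14 arrays, and no biological explanation was tested.

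Skeletal muscle genes differed between the teats of an animal by up to -7.16 in the list mean (mesenchymal tissue of animal 963, inverted minus normal), and by 3.50 and 2.67 in epithelial tissue of animals 964 and 1037 and 1.68 in mesenchymal tissue of animal 1037. A teat effect alike in both tissues would move all pairs of arrays one way, and the pairs did not all go so. In mesenchymal tissue animals 964, 1059 and 1103 had changes of -0.26, -0.73 and -0.18, and in epithelial tissue 3.50, 0.06 and 0.84. These mesenchymal changes were small. The only change below -1, -7.16, rests on 1 array, so this explanation stays open. A teat effect that differs between tissues stays open too: the epithelial minus the mesenchymal change was above 0 in 5 of 5 animals (6.81 in 963, 3.76 in 964, 0.99 in 1037, 0.79 in 1059 and 1.02 in 1103). A different amount of striated muscle in the pieces stays open as well. Where alternate members of the list differed by over 1, at least 85.7% of the other members went the same way. Any cause that moves these genes together would give this, so the share cannot tell the explanations apart. None of these explanations was excluded, and how deep each piece was dissected is not in the labels.

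Of 382 groups of 5 gene values, 26 had an array far from the other 4, and of 138 groups of list means 9; chance flags about 5% of groups, 19 and 7 here. In normal teats of non-affected animals, epithelial tissue, ASPA was 3.72 in animal 950, DSP 7.64 in 1058 and RPS25 12.93 in 1040. In mesenchymal tissue of these animals, CA3 was 12.16 and GADD45A 8.18 in 1058, GAP43 5.00 and TACC3 5.55 in 957, IFIT1 8.57 in 950, and MYLPF 1.15, TNNC2 3.71 and TNNT3 0 in 1040. In normal teats of affected animals, epithelial tissue, CIDEA was 9.36, FASN 12.20, FZD4 9.68, LOC100737483 9.59 and S100A9 7.27 in 1037, EIF2AK2 6.78 in 964, MYH2 10.70 in 963 and ZNF335 5.74 in 1059. In mesenchymal tissue LOC100152327 was 8.01 and STAT5B 8.43 in 1059. In inverted teats, CHGB was 5.41 in epithelial tissue of 1059 and PTHLH 4.66 in that of 1103, and in mesenchymal tissue ASPA was 3.80 in 1103, FOXA2 3.38 in 964 and NR5A1 6.19 in 963. Among list means, in animal 1058 the keratinocyte list was 6.47 and the Wnt list 7.41 in epithelial tissue and the ribosome list 11.90 in mesenchymal tissue. In epithelial tissue the steroid, prolactin and growth hormone list was 6.96 in animal 950, the adipocyte list 9.44 in the normal teat of 1037, and on the inverted teat array of 1103 the keratinocyte list was 5.59, the smooth muscle list 10.41 and the teat development list 6.02. The cell cycle list was 5.50 in the mesenchymal normal teat of 1059.

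The difference between tissues was called for 22 of 69 list tests at the preset correlation and for 0 with an estimated correlation (lowest adjusted p = 0.48 with an estimated correlation); values are median log2 differences, epithelial minus mesenchymal. With 1 animal left out, 3 of the 22 kept their call throughout (skeletal muscle within affected animals and the ribosome in both comparisons of inverted teats), and the medians of 10 changed sign at least once. Within affected animals the called lists were skeletal muscle 2.74 (1.53 without animal 963), ribosome -0.16, respiratory chain -0.20, smooth muscle 0.029, Schwann cell 0.054 and keratinocyte -0.40. For normal teats of affected against non-affected animals they were skeletal muscle -1.20 (-0.32 without animal 1040 and -0.29 without animal 1059, not called), ribosome -0.072, respiratory chain 0.11, melanocyte 0.15, immediate early -0.18, interferon 0.22 and adipocyte 0.25. For inverted against non-affected normal teats they were ribosome -0.24, skeletal muscle 1.51 (-0.19 without animal 963, not called), smooth muscle 0.18, fibroblast -0.41, melanocyte 0.21, Schwann cell 0.079, endothelial 0.041, adipocyte 0.15 and interferon 0.082.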

How the results depend on the processing

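Leaving out the arrays of animals 1103, 963 and 1040 and the covariates CSN2 and KRT were chosen after the data were seen; the other alternatives were planned. The count of 0 probe sets held in all 6 teat comparisons and the 3 differences between tissues under each setting run, with 1 exception: without animal 957 the mesenchymal comparison of normal teats gave 1 (range over animals left out 0 to 1). With the animal as a random replicate block these counts stayed 0, as they did with a fixed block in the comparisons of teats within affected animals. The tissue count ranged from 4402 to 6754 with 1 animal left out and was 5365 to 8124 under the other settings. The 18 list calls fell to 0 with an estimated inter-gene correlation and ranged from 12 to 30 with 1 animal left out, 30 without animal 1059; the cause was not tested. Other settings gave 21 calls with the mean of all probe sets per gene or the animal as a replicate block, 16 with quantile normalization, 17 with no filter, 16 without the epithelial inverted array of 1103, 14 without the mesenchymal arrays of 963 (inverted) and 1040, and 22 with either covariate.

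Called lists whose direction turned follow, and the cause was not tested beyond the array left out. With quantile normalization the ribosome list in epithelial inverted against non-affected normal teats had a median of -0.0083, and only the direction of its test turned. Without the epithelial inverted array of 1103, smooth muscle had -0.050 within affected animals and -0.034 against non-affected animals, and endothelial -0.036 within affected animals. Without the mesenchymal arrays of 963 and 1040, skeletal muscle in mesenchymal normal teats had -0.13. With KRT as a covariate endothelial within affected animals had -0.045 and mesenchymal adipocyte 0.034; epithelial smooth muscle within affected animals had 0.015, endothelial against non-affected animals 0.10, leukocyte 0.15 and immediate early -0.14, and these 4 lost their calls. With 1 animal left out, medians ranged as follows: in mesenchymal tissue skeletal muscle from -2.20 to 0.25 within affected animals and from -0.13 to 1.92 between normal teats, adipocyte from -0.34 to 0.14 and cell cycle from -0.0029 to 0.26; in epithelial tissue respiratory chain between normal teats from -0.0041 to 0.13, smooth muscle against non-affected animals from -0.034 to 0.42 and within affected animals from 0.08 to 0.31, and endothelial within affected animals from -0.043 to 0.18.

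Of the values of called lists under the alternatives, 250 kept direction and call, 60 kept the direction without the call and 14 turned. Among the settings in which lists were tested, some calls were lost only with an estimated correlation. These were epithelial skeletal muscle in both comparisons, the epithelial respiratory chain within affected animals and the mesenchymal ribosome against non-affected animals. The lists were not tested with the added offset, the stricter filter, the unmoderated model, array weights or breed as a covariate. Nor were they tested in the largest breed cross alone, with other sets of samples or with the fixed replicate block. Of the named genes of the teat comparisons, 2325 values kept direction and side of the threshold, 43 turned in sign without passing it, and TACC3 passed once, at 1.56 without animal 957. Of those of the tissue comparison 985 stayed and 41 no longer passed, among them EIF2AK2, IFIT1, RPS15A, LYVE1 and CBR1, and in 1 setting each MFAP5, VEGFB, LAMC1 and CXCR4. Values near the floor of 0 limit the range over which skeletal muscle and milk genes can be measured.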

Other observations

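The values below were looked up after the milk gene pattern had been seen. Beyond beta-casein, other milk protein genes were high on the arrays of animals 950, 957, 963 and 964. CSN1S1, alpha-S1-casein, lay between 8.54 and 12.42 on these arrays and between 0 and 6.31 on those of the other 6 animals. CSN3, kappa-casein, lay between 6.85 and 11.14 and between 0 and 5.10, and PAEP, the gene of a milk whey lipocalin, between 9.94 and 13.34 and between 2.98 and 8.43. LALBA, alpha-lactalbumin, the regulator of lactose synthesis, showed no such level, with 4.77 to 6.27 and 4.49 to 5.84. Both tissues and both teat types of an animal shared its level: in animal 964 CSN2 was 13.16 and 15.33 in epithelial and 16.14 and 16.17 in mesenchymal tissue.

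Luminal keratins were also present in mesenchymal pieces. KRT19 was 10.48 to 12.05 in the mesenchymal tissue of animals 950, 957, 963 and 964, near the 9.91 to 11.76 of the epithelial arrays other than the inverted teat of 1103, which had 6.87. In mesenchymal tissue of the other animals KRT19 was 1.61 in animal 1058, 3.60 and 4.80 in the normal and inverted teat of 1037, 7.80 in 1109 and 8.36 in 1040. In animals 1059 and 1103 it was 6.41 and 3.47 in the mesenchymal tissue of the normal teat and 10.68 and 9.77 in that of the inverted teat. KRT8 followed, with 6.91 and 3.66 against 10.02 and 8.88 in these animals.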
